A study of Mus musculus with 6 samples.

How the data were processed

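Gene expression was measured in megakaryocyte progenitors (MkP) of wild-type C57BL/6 mice with Affymetrix oligonucleotide arrays, 1 array per sample. Per the labels, 3 samples came from the bone marrow of adult mice and 3 from fetal liver, and in both tissues the cells were flow sorted by the absence of lineage markers and of a stem cell antigen and by the presence of KIT, CD150 and CD41. The labels call the samples biological replicates and give no number of animals or embryos per sample. The p-values therefore measure the spread between these samples, whatever each pooled. Groups were taken from the sample labels alone.

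The deposited values are probe set intensity signals on a linear scale, which the authors computed with MAS5 per the submitters' processing notes. The MAS5 version, scaling target and any later filter are not given in the sources used here. The table held 45101 probe sets, of which 64 were array controls. On every array the mean signal after trimming 2% at each end was 500, so the arrays had been scaled to a common mean before deposit. No detection calls were used here. A signal was called above background on an array when it exceeded the highest signal of the 27 bacterial control probe sets of that array, which lay between 22.2 and 35.1. No pair of arrays had an identical signal for any probe set compared.

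Signals were converted to log2(signal + 2.87), where 2.87 is the 10th percentile of all signals, and no further scaling was applied because the arrays' median log2 signals differed by less than 0.5. A fold change on this scale understates the change of dim genes. Of 45037 probe sets other than controls, 27022 had a mean log2 signal above the 40th percentile and were kept. Gene names came from the platform annotation, in which 34958 probe sets had 1 symbol, 932 had several and 9160 were not listed. The gene identifiers of 34754 probe sets were found in the GRCm38.p6 gene table, and 0 symbols needed an update. Each gene was represented by its kept probe set with the highest mean, which left 11625 genes from 22408 probe sets. This choice was made anew in each alternative, so leaving out an array can change the probe set of a gene. Genes called in the comparison had 827 further kept probe sets, of which 758 had the sign of the gene's call and 1 was past the threshold with the opposite sign. No genome build is named for the array values, and no coordinates are given.

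Fetal liver was compared with bone marrow in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. All log2 fold changes are fetal liver minus bone marrow, with the standard error (SE) of the fit. Where a gene was not above background on any of the 3 arrays of a tissue, the change is given as "at least N-fold". That bound sets the mean of the brighter tissue against the mean, in the dimmer one, of the higher of the gene's own signal and the highest control signal of each array. From general knowledge 33 gene lists were written. Of these, 31 had at least 5 measured genes and were tested with camera at its preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The sex-linked genes (4 measured) and the sort markers (3 measured) were described without a test. Of 745 list members, 688 had a named probe set and 563 were measured. Array measures were compared with two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3. Figures were drawn with matplotlib 3.10.9.

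The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 12 genes with the largest change in each direction among genes past the threshold whose 3 values of one tissue all lay above those of the other. From each list it took up to 4 members past the threshold with the largest change, or where none passed the 2 members with the smallest p. It added Kit, Slamf1, Itga2b, Gata1, Pf4, Ifnar1, Igf1r, Lin28b and Xist in any case, and the most abundant members of marker lists. Of these, Lin28b fell below the filter on dim probe sets. 3 further genes of the rule are not reported here.

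On simulated data for the same 11625 genes and 6 arrays, with 200 genes changed, the fetal liver against bone marrow fit recovered 9 of 68 genes changed 2-fold, 37 of 66 changed 4-fold and 63 of 66 changed 16-fold, and called 6 unchanged genes. With no gene changed it called 0 genes. Most changes of 2-fold were therefore missed in this simulation. The data gave 903 calls, at which the adjustment is less strict than with 200 changed genes, so this recovery need not hold for them.

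Alternatives covered the offset, quantile normalization, median centring, the filter, the variance model, the rule for probe sets, the replicate number as a block, each array left out in turn, an estimated inter-gene correlation and fry. A floor at the highest bacterial control signal and covariates for the ratio of the 5' to the 3' control probe set, of Gapdh in one fit and of Actb in another, were added after seeing the data.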

Results

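Megakaryocyte progenitors (MkP) are the sorted blood precursors that give rise to megakaryocytes and, through them, to platelets. The series compared MkP of adult bone marrow (3 arrays, mice aged 12 to 18 weeks) with MkP of fetal liver (3 arrays, E13.5), and asks how gene expression in these progenitors differs between the fetal and the adult organ. Genes of the sort itself were not past the threshold. Itga2b, which encodes CD41, had a mean signal of 4918 ± 654 (SD, n = 3) in marrow and 3205 ± 794 in fetal liver, a log2 fold change of -0.64 ± 0.22 (SE, limma adjusted p = 0.109). Kit differed by -0.55 ± 0.34 (adjusted p = 0.384) and Slamf1, which encodes CD150, by 0.29 ± 0.34 (adjusted p = 0.671). Itga2b was past the threshold with the replicate number as a replicate block (adjusted p = 0.0414) and at -0.79 under the Gapdh covariate chosen after seeing the data (adjusted p = 0.0307; 0.0307 to 0.823 over all alternatives).

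Of 4 array measures compared, 2 separated the tissues without overlap. The median signal was 77.0 ± 3.05 (SD, n = 3) in marrow and 64.2 ± 1.34 in fetal liver (exact permutation p = 0.1, the smallest possible). Probe sets above the bacterial controls made up 65.0% ± 3.39 and 61.6% ± 1.93 (exact permutation p = 0.2). The 5' to 3' signal ratio of Actb was 1.09 ± 0.038 in marrow and 0.961 ± 0.065 in fetal liver (exact permutation p = 0.1). That of Gapdh, a measure of RNA integrity and labelling length, was 0.193 ± 0.103 in marrow and 0.330 ± 0.192 in fetal liver (exact permutation p = 0.3). Across genes, the arrays of fetal liver correlated with each other at 0.939 to 0.963 and those of marrow at 0.901 to 0.921, against 0.849 to 0.878 between tissues. The first principal component (48.4% of the variance) separated the tissues, and the second (18.6%) set marrow replicate 2, with a score of -63.4, apart from the other marrow arrays at 39.3 and 32.7.

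As lists, genes of the fetal haematopoietic programme and imprinted genes were higher in the fetal liver arrays (camera adjusted p = 6.34e-05 and 5.77e-05), though not past the threshold with an estimated correlation (adjusted p = 0.157 and 0.0752). Interferon response, MHC class I and granulocyte and monocyte genes were higher in the marrow arrays (camera adjusted p = 7.45e-14, 6.30e-12 and 7.02e-19), and these were not past it with an estimated correlation either (adjusted p = 0.0556, 0.0752 and 0.0752). Most measured genes of these 3 marrow lists were above background on some fetal liver array too, and 0 of 47, 1 of 17 and 1 of 20 were not. In fetal liver, Igf2bp1, an RNA-binding protein of fetal tissues, and Stc2, a secreted stanniocalcin, were each at least 44.6-fold higher (adjusted p = 5.77e-05 and 3.49e-05). Without fetal liver replicate 1 another probe set stood for Stc2, with a change of 3.37 (log2, adjusted p = 0.0212), against 7.62 for the first probe set on the same arrays. In marrow, Mndal, an interferon-inducible gene of the PYHIN family, was at least 70.5-fold higher (adjusted p = 2.56e-05) and Nlrc5, the transactivator of MHC class I genes, at least 55.3-fold (adjusted p = 5.77e-05). Of 11625 genes, 903 were past the threshold in limma, 350 higher in fetal liver and 553 higher in marrow. Of the former 27, and of the latter 56, were not above background on any array of the other tissue.

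The other leading genes of fetal liver were Ddah1, which degrades inhibitors of nitric oxide synthase (at least 27.8-fold, adjusted p = 1.47e-04), Cntn3 (at least 13.7-fold, adjusted p = 0.0011), Sfrp2, a secreted modulator of Wnt signalling (at least 9.79-fold, adjusted p = 4.98e-04), Kif26a (at least 8.81-fold, adjusted p = 5.11e-04) and the RNA gene Redrum (at least 6.38-fold, adjusted p = 9.59e-04). Hif3a rose by 6.46 ± 0.61 on the log2 scale (SE, adjusted p = 2.06e-04), Slc30a10, a manganese exporter, by 5.68 ± 0.87 (adjusted p = 0.00348) and Tubb1, the platelet beta tubulin, by 5.11 ± 0.70 (adjusted p = 0.00196). Another probe set stood for Ddah1 without marrow replicate 3 and without fetal liver replicates 2 and 3, with changes of 4.65, 5.15 and 4.86 (log2). Sfrp2, Kif26a and Redrum were each tested in 3 of the 6 fits with an array left out and fell below the filter in the others. Hif3a and Slc30a10 were above background on 1 of the 3 marrow arrays and Tubb1 on 2. The embryonic globin Hbb-y was at least 25.1-fold higher (adjusted p = 0.00951). Hbb-y had a signal of 83.4 in fetal liver replicate 1, against 3064 and 1628 in replicates 2 and 3. Its fetal liver signals were 1592 ± 1491 (SD, n = 3), and its call was lost without probe sets prone to cross-hybridisation (adjusted p = 0.245) and without the variance trend (adjusted p = 0.0524; 8.47e-04 to 0.245 over all alternatives).

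The other leading genes of marrow were H2-Q5 (at least 53.4-fold, adjusted p = 5.56e-05), Ltf, which encodes lactoferrin (at least 38.0-fold, adjusted p = 5.56e-05), Chil3, a chitinase-like protein of myeloid cells (at least 37.7-fold, adjusted p = 1.86e-04), Ifi209 (at least 17.4-fold, adjusted p = 2.06e-04) and the inhibitory receptor Lair1 (at least 12.5-fold, adjusted p = 2.06e-04). Aldh1a1, a retinaldehyde dehydrogenase, fell by 6.37 ± 0.48 on the log2 scale in fetal liver (adjusted p = 5.77e-05), where 1 of 3 arrays was above background. H2-Q5, Mndal and Ifi209 belong to families of closely similar genes, so which member was measured is uncertain. Without marrow replicate 2 another probe set stood for Ifi209, with a change of -4.74 (log2).

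The counts depended on scaling and on which arrays were used. Median centring moved the median change of all genes by 0.25 (log2) towards fetal liver and gave 897 genes higher there and 438 higher in marrow, so that marrow held 32.8% of the calls against 61.2% without it. The count for fetal liver was 177, 106 and 103 without fetal liver replicates 1, 2 and 3, against 306, 262 and 320 without marrow replicates 1, 2 and 3. The count for marrow was 336 and 317 without fetal liver replicates 2 and 3, against 418, 428 and 377 without marrow replicates 1, 2 and 3. With the 5' to 3' ratio of Actb as a covariate, chosen after seeing the data, 10 genes were higher in fetal liver and 42 in marrow, and all 52 were among the 903. That ratio follows the tissue closely (correlation -0.822), so this fit leaves little of the difference between tissues to test.

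Interferon-inducible genes and the MHC class I pathway were lower in the fetal liver arrays. Of 47 measured interferon response genes, 43 had a negative log2 fold change, 22 fell past the threshold over all genes (28 adjusted over the list alone) and 0 rose. The 22 became 14 and 12 without marrow replicates 1 and 3, and 12 and 14 without fetal liver replicates 2 and 3. The list's median was -1.36 (camera adjusted p = 7.45e-14; adjusted p = 0.0556 with an estimated correlation). Rsad2, which encodes viperin, fell by 5.27 ± 0.69 (SE, adjusted p = 0.00139), Sp100, a nuclear body protein, by 4.73 ± 0.42 (adjusted p = 1.86e-04) and Gbp3, a guanylate-binding protein, by 3.78 ± 0.56 (adjusted p = 0.00294). Rsad2 and Gbp3 were above background on 1 of the 3 fetal liver arrays and Xaf1 on 2. Xaf1 fell by 3.44 ± 0.88 (adjusted p = 0.0406). Its call was lost in 4 of the 6 fits with an array left out, those without each marrow array (adjusted p = 0.0817, 0.0979 and 0.0907) and without fetal liver replicate 2 (0.0582), within 0.00654 to 0.884 over all alternatives. Of 17 measured MHC class I genes, 9 fell (10 adjusted over the list alone) and 0 rose. The median was -1.45 (camera adjusted p = 6.30e-12; adjusted p = 0.0752 with an estimated correlation). The immunoproteasome subunit Psmb9 had a signal of 7092 ± 954 (SD, n = 3) in marrow and 573 ± 103 in fetal liver, a change of -3.63 ± 0.23 (adjusted p = 2.56e-05). Tap1, a subunit of the peptide transporter, fell by 3.15 ± 0.33 (adjusted p = 4.66e-04) and Psmb8 changed by -2.76 ± 0.26 (adjusted p = 2.08e-04). Genes of granulocytes and immediate-early genes, described with their values in the paragraphs on those lists, were also higher in the same marrow arrays.

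**Figure D1:**
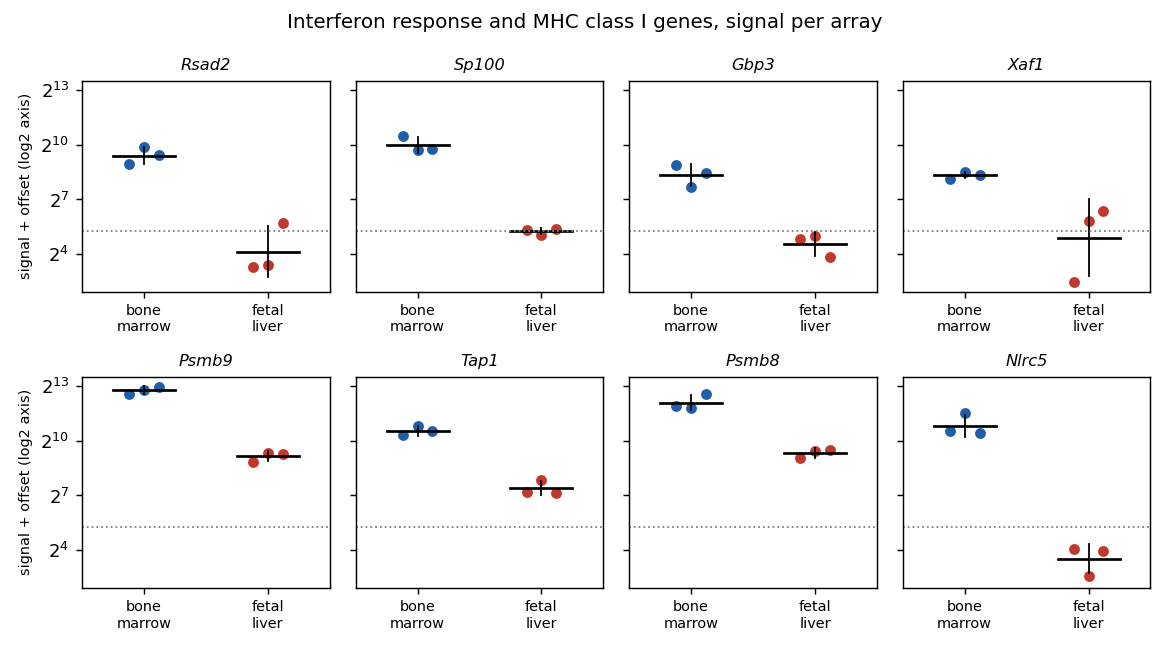
Signal plus the offset of 2.87 (log2 axis) of 8 interferon response and MHC class I genes on each array, with blue points for the 3 bone marrow and red points for the 3 fetal liver arrays, the horizontal bar at the mean and the vertical bar at 1 SD of the log2 values. The dotted line is the highest bacterial control signal of any array (35.1) plus the offset; for each gene the 3 marrow points lie above the 3 fetal liver points.

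The receptors and signal carriers upstream of this response were not past the threshold as a list in camera. Among 26 measured interferon receptor and JAK-STAT genes the median change was -0.17, which turned to 0.08 under median centring (camera adjusted p = 0.124). The list was past it with the filter at the 60th percentile (adjusted p = 0.0473) and by fry (adjusted p = 0.0445; 0.0445 to 0.287 over all alternatives), with 2 members higher in fetal liver and 2 higher in marrow over all genes, and 2 and 2 adjusted over the list alone. The 2 higher in fetal liver became 1 without marrow replicate 1 and 0 without marrow replicate 2 and each fetal liver array, and the 2 higher in marrow became 1 without fetal liver replicate 2. Irf8, a transcription factor of the myeloid lineage, fell by 3.91 ± 0.53 (SE, adjusted p = 0.00178). The receptor chain Ifnar2 fell by 1.16 ± 0.22 (adjusted p = 0.0108); this call was lost without fetal liver replicate 2 (adjusted p = 0.0587) and with the mean of its probe sets (adjusted p = 0.212; 0.00929 to 0.23 over all alternatives). For Ifnar1 the change was -0.72 ± 0.42 (adjusted p = 0.355).

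Granulocyte and monocyte genes were the most strongly shifted list, and all 20 measured members had a lower mean in fetal liver. Of these, 15 fell (16 adjusted over the list alone). The median was -3.38 (camera adjusted p = 7.02e-19; adjusted p = 0.0752 with an estimated correlation). The alarmins S100a9 and S100a8 had signals of 9793 ± 2471 and 6783 ± 1683 (SD, n = 3) in marrow and 195 ± 261 and 94.5 ± 66.9 in fetal liver (adjusted p = 0.00545 and 1.45e-04), where each was above background on 2 of 3 arrays. The secondary granule genes Camp and Ngp fell by 6.44 ± 0.89 and 6.25 ± 0.56 (SE, adjusted p = 0.00207 and 1.86e-04). Each was above background on 1 of the 3 fetal liver arrays. Mpo, the myeloperoxidase of primary granules, fell by 2.23 ± 0.36 (adjusted p = 0.00463) and Lyz2, lysozyme, by 2.42 ± 0.22 (adjusted p = 1.89e-04), and both stayed well above background in fetal liver at 3558 ± 1284 and 1326 ± 189 (SD, n = 3).

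Genes of mast cells, basophils and eosinophils fell in 3 of 9 measured cases (5 adjusted over the list alone). The median was -1.78, or -0.95 over 16 genes with no filter (camera adjusted p = 5.07e-05; adjusted p = 0.0926 with an estimated correlation). These were Prg2, the eosinophil major basic protein (at least 17.6-fold, adjusted p = 8.70e-04), the basophil protease Mcpt8 (at least 12.2-fold, adjusted p = 0.00119) and the IgE receptor chain Ms4a2 (-2.87 ± 0.45, adjusted p = 0.0037). Among 9 macrophage genes 3 fell (5 without marrow replicate 2), also 3 adjusted over the list alone. The median was -1.45 (camera adjusted p = 0.00318; adjusted p = 0.206 with an estimated correlation). The list was no longer past the threshold without marrow replicate 3 (adjusted p = 0.113, median -0.78; 3.10e-04 to 0.206 over all alternatives), and its median was -2.60 without marrow replicate 2. Csf1r fell by 3.08 ± 0.39 (adjusted p = 0.00123) and Cd163, a haemoglobin scavenger receptor, was at least 5.85-fold lower (adjusted p = 0.00782), while C1qb differed by -1.63 ± 0.94 (adjusted p = 0.346; 0.0225 without marrow replicate 2, 0.0225 to 0.679 over all alternatives). Of the 9 macrophage genes 3 stand in another list too, Csf1r among them.

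Megakaryocyte and platelet genes moved both ways. Of 34 measured megakaryocyte and platelet genes, 7 rose and 4 fell in fetal liver (9 and 7 adjusted over the list alone), and the list as a whole was not past the threshold (median 0.22, or -0.03 without fetal liver replicate 3, camera adjusted p = 0.221). The 7 became 4 and 3 without fetal liver replicates 2 and 3. Thbs1, thrombospondin, rose from a signal of 197 ± 58.9 to 5234 ± 881 (SD, n = 3), a log2 change of 4.74 ± 0.29 (SE, adjusted p = 2.56e-05), and Tubb1 rose as given above. Selp, the granule adhesion receptor P-selectin, fell by 3.66 ± 0.53 (adjusted p = 0.00273). The chemokine Pf4, among the most abundant transcripts at 21122 ± 1549 in marrow and 16945 ± 1915 in fetal liver (SD, n = 3), differed by -0.32 ± 0.14 (adjusted p = 0.212), and the integrin chain Itgb3 by 0.34 ± 0.16 (adjusted p = 0.235; 0.0443 under median centring, 0.0443 to 0.927 over all alternatives).

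Of 26 transcription factors of the megakaryocyte and erythroid lineages 1 rose and 2 fell (2 and 3 adjusted over the list alone). Without marrow replicate 2 the count of risen genes was 2, and with any of marrow replicates 1, 2 and 3 and fetal liver replicates 1, 2 and 3 left out 1 gene fell. The median was -0.29 (camera adjusted p = 0.124; 0.0307 under quantile normalization, 0.0307 to 0.999 over all alternatives). The erythroid factor Klf1 rose from 312 ± 47.5 to 1693 ± 391 (SD, n = 3), a change of 2.42 ± 0.29 (SE, adjusted p = 9.44e-04). Erg, a factor of stem cells and megakaryocytes, fell by 1.80 ± 0.33 (adjusted p = 0.00865; 0.0536 without the variance trend, 0.133 with the Actb covariate and 0.00119 to 0.133 over all alternatives). Gata1 differed by 0.95 ± 0.30 (adjusted p = 0.0815), and was past the threshold without marrow replicate 2 (adjusted p = 0.0401), with the replicate block (adjusted p = 0.0313) and under median centring (adjusted p = 0.0303; 0.0303 to 0.277 over all alternatives).

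Erythroid genes were higher in the fetal liver arrays. Sorted bulk RNA cannot tell expression within MkP from that of admixed erythroid cells. Of 29 measured, 9 rose (16 adjusted over the list alone) and 0 fell. The 9 became 4, 2 and 3 without fetal liver replicates 1, 2 and 3. The median was 1.01 (camera adjusted p = 3.16e-08; adjusted p = 0.157 with an estimated correlation). Besides Klf1 and Hbb-y, the ammonium channel component Rhag rose by 2.97 ± 0.67 (SE, adjusted p = 0.0241), from a level above background on 2 of the 3 marrow arrays. Its call was lost without each of fetal liver replicates 1, 2 and 3 (adjusted p = 0.0579, 0.114 and 0.0698; 0.00956 to 0.402 over all alternatives). Genes of haem synthesis and iron handling, of which 7 of 18 stand in another list, rose in 5 cases (6 adjusted over the list alone) and fell in 0. The 5 became 3 without each of marrow replicates 1, 2 and 3, and 3, 1 and 2 without fetal liver replicates 1, 2 and 3. The median was 0.77 (camera adjusted p = 9.24e-04; adjusted p = 0.157 with an estimated correlation). Cpox, an enzyme of haem synthesis, rose by 1.58 ± 0.28 (adjusted p = 0.00744).

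The fetal haematopoietic programme was expressed at higher levels in the fetal liver arrays. Of 10 measured members 5 rose and 0 fell (5 and 1 adjusted over the list alone). The median was 1.76 (camera adjusted p = 6.34e-05; adjusted p = 0.157 with an estimated correlation). It was 2.50 and 1.05 without marrow replicates 2 and 3, and 1.03 and 1.09 without fetal liver replicates 1 and 2. Igf2bp3, a further RNA-binding protein of the Igf2bp1 family, rose from 233 ± 31.0 to 2756 ± 290 (SD, n = 3), a change of 3.55 ± 0.26 (SE, adjusted p = 5.65e-05), and the chromatin protein Hmga2 rose by 3.86 ± 0.43 (adjusted p = 5.97e-04). Lin28b, a regulator of let-7 microRNAs, fell below the filter, with signals of 0.554, 1.41 and 7.67 in marrow and 23.1, 39.6 and 31.7 in fetal liver. Imprinted genes, of which 7 of 17 stand in another list, rose in 6 cases (8 adjusted over the list alone) and fell in 0. The 6 became 3 without fetal liver replicate 1 and 3 without replicate 3. The median was 0.97 (camera adjusted p = 5.77e-05; adjusted p = 0.0752 with an estimated correlation). Peg3 rose by 4.47 ± 0.46 (adjusted p = 4.11e-04), from a level above background on 1 of the 3 marrow arrays, the growth factor Igf2 was at least 5.62-fold higher (adjusted p = 0.00791), and Dlk1 was at least 5.25-fold higher (adjusted p = 0.00419). Without marrow replicate 2 another probe set stood for Igf2, with a change of 2.96 (log2). Igf2 was tested in 3 of the 6 fits with an array left out. The call of Dlk1 was lost without fetal liver replicate 1 (log2 change 1.05, adjusted p = 0.471; 0.00315 to 0.471 over all alternatives), where another probe set stood for the gene. The first probe set had a change of 4.04 on the same arrays. In insulin-like growth factor signalling 2 of 20 measured genes rose and 1 fell (4 and 4 adjusted over the list alone). The 2 became 1 without each of fetal liver replicates 1, 2 and 3, and the 1 became 0 without marrow replicate 2 and fetal liver replicates 2 and 3. Its median of -0.26 and mean of 0.23 had opposite signs, and the list was not past the threshold (camera adjusted p = 0.997). The adaptor Grb10 rose by 2.65 ± 0.31 (adjusted p = 7.43e-04), and the receptor Igf1r differed by 0.36 ± 0.17 (adjusted p = 0.261).

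HOX genes and several stem cell genes were lower in the fetal liver arrays. Of 9 measured HOX genes 3 fell (6 adjusted over the list alone) and 0 rose. The median was -2.12 (camera adjusted p = 6.90e-05; adjusted p = 0.0752 with an estimated correlation). With no filter, which brings in dim genes, it was -0.73 over 20 genes (adjusted p = 0.0023), and -1.42 with the floor. Hoxa9 fell from 1496 ± 282 to 89.3 ± 40.5 (SD, n = 3), a change of -4.13 ± 0.44 (SE, adjusted p = 4.66e-04), and Hoxb4 fell by 2.72 ± 0.54 (adjusted p = 0.0134). Haematopoietic stem cell genes, of which 11 of 22 stand in another list, moved both ways, with 4 higher in fetal liver and 8 higher in marrow (5 and 12 adjusted over the list alone). The 4 became 2 without fetal liver replicate 1 and 2 without replicate 3. Their median was -0.71 (camera adjusted p = 0.018; adjusted p = 0.119 with an estimated correlation). The list was not past the threshold without marrow replicate 1 (adjusted p = 0.0686) or 2 (adjusted p = 0.0586), or with the Actb covariate (adjusted p = 0.122; 0.00126 to 0.122 over all alternatives). Mecom and Hlf were above background on 2 of the 3 fetal liver arrays. Mecom fell by 3.74 ± 0.69 (adjusted p = 0.0091), and Fgd5 was at least 6.52-fold higher in fetal liver (adjusted p = 7.97e-04). Hlf fell by 3.61 ± 0.61 (adjusted p = 0.00578), but by 1.67 without marrow replicate 2 (adjusted p = 0.0767; 0.0015 to 0.255 over all alternatives), where another probe set stood for it. The first probe set of Hlf had a change of -3.31 on those arrays.

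**Figure D2:**
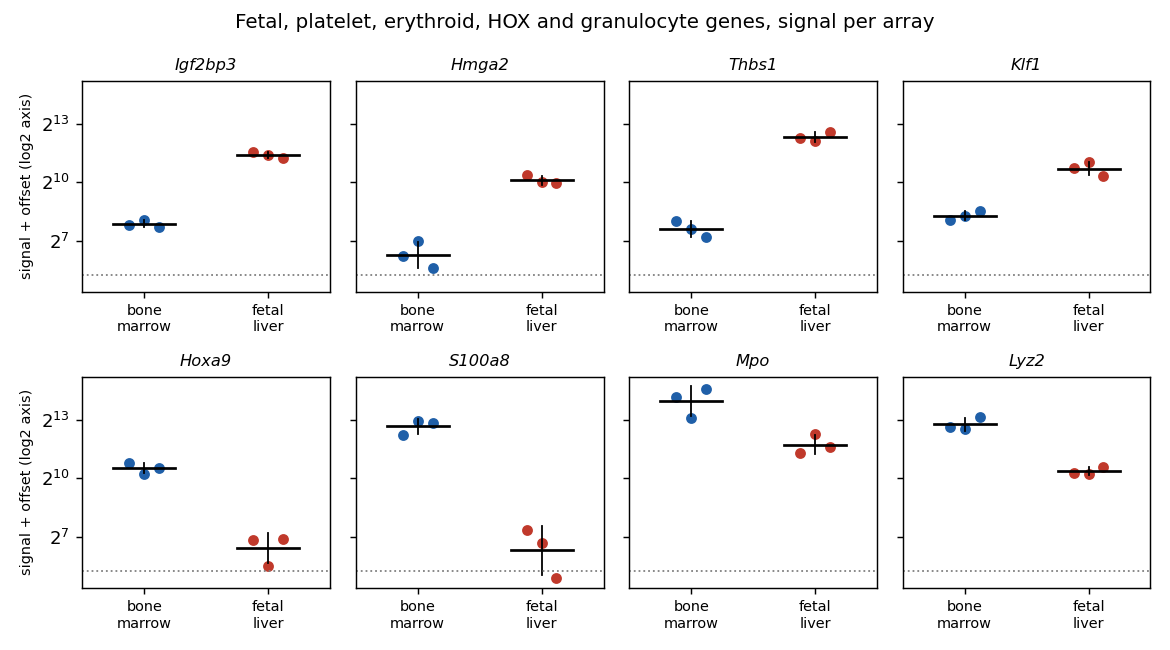
Signal plus the offset of 2.87 (log2 axis) of 8 genes of the fetal programme, platelets, the erythroid lineage, the HOX clusters and granulocytes on each array, with blue points for the 3 bone marrow and red points for the 3 fetal liver arrays, the horizontal bar at the mean and the vertical bar at 1 SD of the log2 values. The dotted line is the highest bacterial control signal of any array (35.1) plus the offset; Mpo is far above it in both tissues, at 17513 in marrow and 3558 in fetal liver.

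Proliferation genes were slightly higher, and inhibitors of the cell cycle lower, in the fetal liver arrays. Of 37 DNA replication genes 2 rose and 0 fell, also 2 adjusted over the list alone. The 2 became 1 without marrow replicate 1 and 0 without each of fetal liver replicates 1, 2 and 3. The median was 0.32 (camera adjusted p = 0.00139; adjusted p = 0.143 with an estimated correlation). With the Actb covariate it was 0.13 and the list lost its call (adjusted p = 0.289; 2.44e-05 to 0.289 over all alternatives). Of 25 mitotic genes 1 rose and 0 fell (4 adjusted over the list alone). That count was 3 without fetal liver replicate 1 and 0 without replicates 2 and 3. The median was 0.31 (camera adjusted p = 0.00213; adjusted p = 0.0839 with an estimated correlation). Among 26 MYC targets and ribosome biogenesis genes 2 rose and 0 fell, also 2 adjusted over the list alone. The 2 became 0 without marrow replicates 1 and 2 and without fetal liver replicates 1, 2 and 3. The median was 0.41 (camera adjusted p = 8.68e-04; adjusted p = 0.0752 with an estimated correlation). With the Actb covariate it was 0.35 and the list lost its call (adjusted p = 0.08; 1.01e-04 to 0.08 over all alternatives). Cyclin E1 (Ccne1) rose by 2.14 ± 0.36 (SE, adjusted p = 0.00545), a call lost without marrow replicate 1 (adjusted p = 0.0732) and without fetal liver replicates 1, 2 and 3 (adjusted p = 0.0747, 0.17 and 0.112; 0.00256 to 0.17 over all alternatives), and in each of these fits another probe set stood for it. On those arrays, in the same order, the first probe set of Ccne1 had changes of 1.96, 2.32, 1.91 and 2.19 (log2). The spindle factor Tpx2 rose by 0.82 ± 0.17 (adjusted p = 0.0183), a call lost without marrow replicate 3 (adjusted p = 0.0529) and without fetal liver replicates 2 and 3 (adjusted p = 0.0983 and 0.0944; 0.0058 to 0.273 over all alternatives). Of 18 cell cycle inhibitor and quiescence genes 4 fell (8 adjusted over the list alone) and 0 rose. The 4 became 2 without marrow replicate 2 and 2 without fetal liver replicate 2. The median was -0.61 (camera adjusted p = 6.98e-04; adjusted p = 0.0752 with an estimated correlation). The inhibitor Cdkn2c, p18, fell by 2.67 ± 0.34 (adjusted p = 0.00125) and the transcription factor Klf6 by 1.99 ± 0.27 (adjusted p = 0.00174).

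Glycolysis and hypoxia response genes rose in 5 of 20 measured cases (10 adjusted over the list alone) and fell in 0. The median was 0.53 (camera adjusted p = 1.19e-05; adjusted p = 0.0926 with an estimated correlation). Slc16a3, a lactate exporter, rose by 3.42 ± 0.51 (SE, adjusted p = 0.00297) and Bnip3, a mitophagy receptor induced by hypoxia, by 1.82 ± 0.27 (adjusted p = 0.00273). Of 34 oxidative phosphorylation genes 1 rose, and 0 adjusted over the list alone. The count was 3 without marrow replicate 1 and 0 without marrow replicates 2 and 3 and fetal liver replicates 1, 2 and 3. The median was 0.23 (camera adjusted p = 0.00176; adjusted p = 0.331 with an estimated correlation). It lost its call without marrow replicate 2 (adjusted p = 0.0612) and by fry (adjusted p = 0.106). With the Actb covariate its median was -0.03 and the call was lost too (adjusted p = 0.71; 1.80e-05 to 0.71 over all alternatives), so the direction itself depends on that choice. The gene called was Ndufs1, a subunit of complex I (1.04 ± 0.27, adjusted p = 0.0445), whose call was lost without marrow replicates 2 and 3 (adjusted p = 0.0812 and 0.0672) and fetal liver replicates 1, 2 and 3 (adjusted p = 0.0937, 0.14 and 0.173; 0.0138 to 0.6 over all alternatives). Of 19 cholesterol biosynthesis genes 1 rose, also 1 adjusted over the list alone. The count was 0 without marrow replicate 2 and fetal liver replicates 1, 2 and 3. The median was 0.49 (camera adjusted p = 0.0297; adjusted p = 0.168 with an estimated correlation). The list lost its call without marrow replicate 1 or 2 or fetal liver replicate 1 (adjusted p = 0.0686, 0.0912 and 0.0659). With the Actb covariate the median was 0.29 and the call was lost too (adjusted p = 0.402; 0.0102 to 0.402 over all alternatives). Its member was Pmvk, phosphomevalonate kinase (0.86 ± 0.21, adjusted p = 0.0306), whose call was lost without marrow replicates 2 and 3 and fetal liver replicates 1, 2 and 3 (adjusted p = 0.0663, 0.0651, 0.0845, 0.136 and 0.0921; 0.00867 to 0.491 over all alternatives).

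Immediate-early and heat shock genes, which respond within minutes to cell handling, were higher in the marrow arrays. Of 20 measured, 9 fell in fetal liver (12 adjusted over the list alone; 5 without marrow replicate 3) and 0 rose. The median was -1.82, or -1.34 with the members below background in one tissue set at their bounds (camera adjusted p = 1.43e-08; adjusted p = 0.124 with an estimated correlation). Fos fell by 4.22 ± 0.63 (SE, adjusted p = 0.00306), Nr4a1 by 3.77 ± 0.71 (adjusted p = 0.00993) and Egr1 by 2.51 ± 0.43 (adjusted p = 0.00642). Nr4a1 was above background on 1 of the 3 fetal liver arrays. Of 17 NF-kB and inflammatory genes 5 fell (7 adjusted over the list alone) and 0 rose. The 5 became 3 and 1 without marrow replicates 1 and 3, and 3 and 2 without fetal liver replicates 2 and 3. The median was -1.19 (camera adjusted p = 1.40e-04; adjusted p = 0.0752 with an estimated correlation), among them Tnfaip3, a feedback inhibitor of NF-kB (-2.95 ± 0.43, adjusted p = 0.00284). Of 14 progenitor cytokine receptors 6 fell and 0 rose (7 and 1 adjusted over the list alone). Without fetal liver replicate 1 the count of risen genes was 1. The median was -1.53 (camera adjusted p = 3.06e-06; adjusted p = 0.0752 with an estimated correlation). The chemokine receptor Cxcr4, which retains progenitors in marrow, fell from 9586 ± 1069 to 1179 ± 308 (SD, n = 3), a change of -3.05 ± 0.22 (adjusted p = 5.65e-05), and Il6ra fell by 3.23 ± 0.59 (adjusted p = 0.0091) to a level above background on 2 of 3 arrays. In TGF-beta and BMP signalling 1 of 19 genes rose and 2 fell (1 and 4 adjusted over the list alone). The 2 became 1 without marrow replicates 1 and 3 and fetal liver replicate 1. The median was -0.29 (camera adjusted p = 0.128). This list was past the threshold in 5 of 22 alternatives, without fetal liver replicates 2 and 3 (adjusted p = 0.0425 and 0.032), with the filter at the 60th percentile (adjusted p = 0.0473), with the floor (adjusted p = 0.0356) and by fry (adjusted p = 0.0228; 0.0228 to 0.337 over all alternatives). Ltbp1, which anchors latent TGF-beta, rose by 1.52 ± 0.26 and Smad1 fell by 1.67 ± 0.29 (both adjusted p = 0.00706).

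The marker lists of B-lymphoid, T and NK, endothelial, stromal and hepatocyte cells were not past the threshold in camera, though each was in at least 1 alternative. For 7 B-lymphoid genes the median was -0.53 (camera adjusted p = 0.0595) with 1 member lower in fetal liver (2 adjusted over the list alone; 2 without marrow replicate 3), Dntt, the terminal transferase of lymphoid progenitors (at least 5.97-fold, adjusted p = 0.0042). This list was past the threshold in 7 of 21 alternatives, among them those without marrow replicate 3 (adjusted p = 0.0461) and fetal liver replicate 2 (adjusted p = 0.0195) and fry (adjusted p = 0.00409; 0.00409 to 0.168 over all alternatives). For 7 T and NK cell genes the median was -0.20, which turned to 0.05 under median centring and to 0.01 under quantile normalization (camera adjusted p = 0.115), with Nkg7 lower in fetal liver (-3.28 ± 0.36, SE, adjusted p = 5.44e-04), also the 1 call adjusted over the list alone. It was past the threshold with no filter (adjusted p = 0.00625), with the floor (adjusted p = 0.0373) and by fry (adjusted p = 0.0497; 0.00625 to 0.364 over all alternatives). For 8 endothelial genes the median was 0.60 (camera adjusted p = 0.122; 0.0465 without fetal liver replicate 3, 0.00341 by fry and 0.00341 to 0.361 over all alternatives), with 2 higher and 1 lower, the same numbers adjusted over the list alone, and Egfl7 rose by 2.18 ± 0.25 (adjusted p = 6.83e-04). The 2 became 1 without fetal liver replicate 2 and without replicate 3, and the 1 became 0 without marrow replicates 1 and 2 and fetal liver replicates 2 and 3. For 7 stromal and bone cell genes the median was 0.48 (camera adjusted p = 0.122; 0.0425 and 0.0388 without marrow replicates 2 and 3, 0.0384 by fry, 0.0384 to 0.245 over all alternatives), with 1 higher (2 adjusted over the list alone). That gene was Sparc (3.33 ± 0.77, adjusted p = 0.0269; above background on 2 of 3 marrow arrays), whose call was lost without each of fetal liver replicates 1, 2 and 3 (adjusted p = 0.0858, 0.1 and 0.0703; 0.00511 to 0.6 over all alternatives), which left 0 members called. For 7 hepatocyte genes the median was 1.69 (camera adjusted p = 0.122; 0.0316 without fetal liver replicate 3 and 0.0316 to 0.416 over all alternatives), with 1 higher (2 adjusted over the list alone). The count was 0 with any of the 6 arrays left out. Over all alternatives medians ran from 0.03 to 2.11 for hepatocyte, 0.06 to 1.11 for endothelial and 0.04 to 0.96 for stromal genes. Afp, the abundant fetal liver protein, had signals of 310 ± 244 in marrow and 1140 ± 1433 in fetal liver (SD, n = 3), a change of 1.81 ± 1.09 (adjusted p = 0.365). Apoa1 was the called gene (2.51 ± 0.67, adjusted p = 0.0481; above background on 2 of 3 marrow arrays), and its call was lost without each of marrow replicates 1, 2 and 3 (adjusted p = 0.0545, 0.109 and 0.0734) and fetal liver replicates 1, 2 and 3 (adjusted p = 0.117, 0.19 and 0.113; 0.0205 to 0.306 over all alternatives). Another probe set stood for Apoa1 without marrow replicate 2 and without fetal liver replicate 2. It had changes of 1.49 and 2.44 (log2), against 2.94 and 2.36 for the first probe set.

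Xist, the RNA of the inactive X chromosome, was higher in fetal liver by 7.20 ± 0.40 (SE, adjusted p = 2.56e-05), with signals of 43.0, 17.7 and 20.5 in marrow and 4389, 3854 and 4097 in fetal liver. It was above background on 1 of the 3 marrow arrays. The Y-linked genes Eif2s3y (-0.60 ± 0.33, adjusted p = 0.323) and Kdm5d (-1.15 ± 0.33, adjusted p = 0.0568; 0.0337 without fetal liver replicate 1, 0.0377 with the replicate block, 0.0493 with the floor, 0.0337 to 0.37 over all alternatives) were above background on all 6 arrays.

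**Figure D3:**
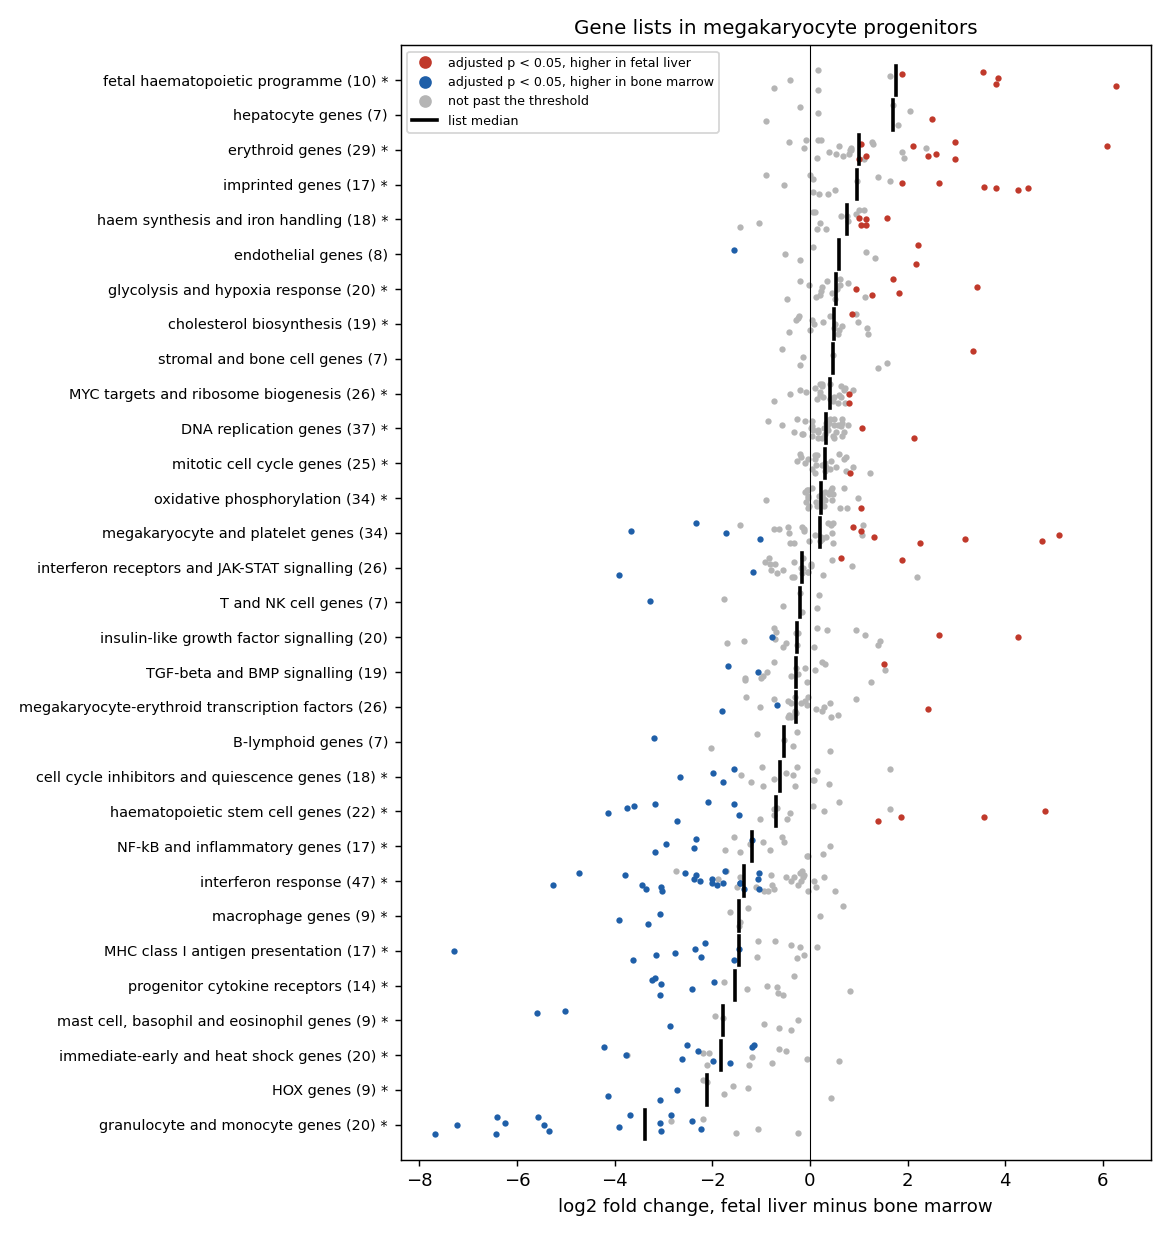
Log2 fold change, fetal liver minus bone marrow, of each measured member of the 31 tested gene lists, with the number of members in brackets, the black bar at the list median and an asterisk for lists with a camera adjusted p under 0.05. Red and blue points are genes past the threshold in limma, higher in fetal liver and in marrow; medians run from -3.38 for granulocyte and monocyte genes to 1.76 for the fetal haematopoietic programme.

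In all, 21 of the 31 lists were past the threshold with camera's preset correlation, 10 towards fetal liver and 11 towards marrow. With the Actb covariate 16 of the 21 stayed past it and 5 did not. With an estimated correlation 0 were past it. The estimates were 0.0141 for interferon response and -0.00305 for HOX genes, against the preset 0.01. Some other lists had higher estimates, at 0.305 for granulocyte and monocyte genes, 0.337 for the fetal haematopoietic programme and 0.263 for erythroid genes. For those lists the camera adjusted p at the preset rests on a correlation well below the estimate. Fry, which tests whether a list's genes move on balance one way without comparing them with other genes, called 26.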

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

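The tests of the 3 patterns below were chosen after the results were seen, and the count over other splits of the arrays was planned. Beyond the genes compared in the report, 4614 kept probe sets carried no single gene name (619 with several genes, 3995 not listed in the annotation). In a separate limma fit of all 27022 kept probe sets, 152 of them were higher in marrow and 49 higher in fetal liver. With an unadjusted p under 0.05 there were 893. That fit called 886 of all kept probe sets higher in marrow and 482 higher in fetal liver. The probe sets with no single gene thus hold signal that the report's comparison of genes does not use. For their number they were called no more often than kept probe sets as a whole.

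Granulocyte genes were higher in the marrow arrays, and 20 of the 20 measured members went that way. Mature neutrophils as the whole source are argued against by the primary granule genes Mpo, Elane, Prtn3 and Ctsg, of which the last 3 were chosen after their values were seen. Neutrophils have switched these genes off, yet their median change was -4.20 (log2). Loss of RNA integrity that these ratios follow is argued against as the whole cause by the list's median of -3.67 with the Gapdh 5' to 3' ratio as a covariate and -3.86 with that of Actb, which itself separates the tissues (correlation -0.822) and left 52 genes past the threshold. Granulocytic precursors admixed in the marrow sort and transcripts of these genes within adult MkP cannot be told apart in sorted bulk RNA. The cells were sorted by the absence of lineage markers, but the purity of the sort was not measured here.

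Interferon and MHC class I genes were higher in the same marrow arrays. Array scaling as the whole cause is argued against by the interferon list's median of -1.18 under quantile normalization. The median of -1.11 under median centring adds nothing to this, since centring moves all genes by the same 0.251 (log2). With the Gapdh covariate the list's median was -1.28, which argues against loss of RNA integrity that this ratio follows as the whole cause. With the Actb covariate the median was -1.10, but that fit leaves little of the tissue difference to test and decides nothing here. Admixed granulocytic cells that carry these transcripts cannot be told apart from expression in MkP. In marrow replicate 2 the 31 called interferon and MHC class I genes lay -0.0094 (log2) from the mean of the other marrow arrays, while primary granule genes lay -2.09 and S100a8, S100a9 and secondary granule genes 0.70 from it, and 3 arrays are too few to decide. A difference between fetal and adult MkP or their tissues stays open and untested.

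Xist was high in the fetal liver arrays and near the controls in marrow. A candidate explanation is that the marrow donors were male and each fetal sample pooled embryos of both sexes. The Y-linked genes Eif2s3y, Kdm5d and Uty were above the highest control (35.1) on all 6 arrays, with a lowest fetal liver signal of 129 for Uty. Uty was chosen for this after its values were seen. Sex may therefore be confounded with tissue, and no other gene was tested for it.

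Of the 10 splits of the 6 arrays into 3 and 3, 1 gave 903 genes past the threshold, the real one, and the highest of the others gave 0. With 10 splits no share under 0.05 is possible. Each of the other splits has arrays of both tissues in each group, which puts the tissue difference into the spread within groups. Their 0 calls therefore do not bear on where the difference between tissues comes from.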

How the results depend on the processing

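A floor at the control signal and the Gapdh and Actb covariates were tests chosen after the data were seen. The count of genes higher in fetal liver (350) was 897 under median centring, which by construction moves all genes by 0.251 (log2), and 166 with eBayes without trend (the cause was not tested). With 1 array left out, and so fewer arrays, it was 103 to 320 (177, 106 and 103 without fetal liver replicates 1, 2 and 3). The count higher in marrow (553) was 886 with all kept probe sets, where a gene counts more than once, and 317 to 449 with 1 array left out (336 and 317 without fetal liver replicates 2 and 3). With the Actb covariate, which correlates with the tissue at -0.822 and so leaves little of its difference to test, 10 genes were higher in fetal liver and 42 in marrow, and 16 of the 21 lists stayed past. With an estimated correlation 0 lists were past the threshold in camera and the interferon list's median of -1.36 had adjusted p = 0.0556. Its estimated correlation was 0.0141, near the preset 0.01, and that of HOX genes was -0.00305 (camera adjusted p = 0.0752). For these lists a higher correlation is argued against as the whole cause of the loss. Granulocyte and monocyte genes had an estimate of 0.305 and the fetal haematopoietic programme 0.337, so the same cannot be said of them. By fry 26 lists were past, and with 1 array left out 19 to 24 and a median of -1.43 to -1.23 for the interferon list. With the replicate number as a replicate block 522 genes were higher in fetal liver and 688 in marrow, 885 of the 903 called without it among them, but the arrays' deviations correlated at 0.15, -0.0225 and 0.0809 between equal numbers, so no pairing is assumed. The 131 called genes followed had 2542 values in the alternatives, of which 0 reversed and 393 lost the call, 104 of these with the Actb covariate. Of the 131 genes, 25 kept the call in each alternative that tested them, and 78 in each of these but that covariate. A gene below the filter in a fit was not tested there and does not count as lost. Sfrp2, Kif26a, Redrum, Lair1, Fgd5 and Igf2 were each tested in 3 of the 6 fits with an array left out. Dlk1 was tested in 4 of these fits and Ifi209 in 5. The genes followed without a call had 595 values, of which 19 gained one. Signal over background limits the dim genes, since 59.7% to 68.8% of probe sets were above the controls.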

Other observations

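The lists and tests of this part were chosen after the results were seen, with adjusted p over 6 lists, and the genes named were chosen after their values were seen. Of 11 MHC class II genes 5 were higher in marrow (7 adjusted over the list alone, and 3 over all genes without fetal liver replicate 1), with a median of -2.02 (camera adjusted p = 1.65e-05; adjusted p = 0.0996 with an estimated correlation). Ctss, a lysosomal protease, changed by -5.90 ± 0.75 (SE, adjusted p = 0.00123), H2-Ob by -5.21 ± 0.66 (adjusted p = 0.00123) and the MHC class II regulator Rfx5 by -1.64 ± 0.31 (adjusted p = 0.00994). Ctss and H2-Ob were above background on 1 of the 3 fetal liver arrays. Granulocyte and monocyte genes (median -3.38) and macrophage genes (median -1.45) were also higher in the same marrow arrays. For the lists of this part that were higher in marrow, admixed myeloid cells cannot be told apart from expression in MkP.

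Of 6 Schlafen genes 3 were higher in marrow (4 adjusted over the list alone, and 1 over all genes without fetal liver replicate 3). The median was -2.40, or -1.94 with genes at background set at their bounds (camera adjusted p = 6.15e-04; adjusted p = 0.0996 with an estimated correlation). Slfn8 changed by -4.02 ± 0.59 (SE, adjusted p = 0.00273) and was above background on 2 of 3 fetal liver arrays. Of 9 inflammasome and pyroptosis genes 3 were higher in marrow, also 3 adjusted over the list alone, with a median of -1.07 (camera adjusted p = 7.71e-04; adjusted p = 0.0996 with an estimated correlation). Casp1 was at least 20.4-fold lower in fetal liver (adjusted p = 2.18e-04) and Casp4, above background on 2 of 3 fetal liver arrays, changed by -5.03 ± 0.46 (adjusted p = 1.96e-04). Of 11 toll-like and related receptors 3 were higher in marrow (4 adjusted over the list alone), with a median of -0.94 (camera adjusted p = 0.00381; adjusted p = 0.0996 with an estimated correlation), among them Cd180 (-2.51 ± 0.37, adjusted p = 0.00287) and Ly86 (at least 8.09-fold lower in fetal liver, adjusted p = 0.00706).

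Of 18 actin and smooth muscle type cytoskeleton genes 5 were higher in fetal liver and 0 in marrow (7 and 2 adjusted over the list alone). The 5 became 3 without marrow replicate 2 and fetal liver replicates 1 and 3, and the 0 became 1 without fetal liver replicate 1. The list had a median of 0.37 (camera adjusted p = 0.00424; adjusted p = 0.0996 with an estimated correlation). Myh10, a non-muscle myosin, rose by 3.21 ± 0.29 (SE, adjusted p = 1.86e-04), the calponin Cnn3 by 3.63 ± 0.65 (adjusted p = 0.00812) and Cald1, above background on 2 of 3 marrow arrays, by 4.26 ± 0.72 (adjusted p = 0.00582). Of 18 integrin and leukocyte adhesion genes 3 were higher in marrow, also 3 adjusted over the list alone. The 3 became 1 and 0 without marrow replicates 1 and 3, and 1, 1 and 0 without fetal liver replicates 1, 2 and 3. The list was past the threshold by fry (adjusted p = 0.00572) but not in camera (median -0.38, adjusted p = 0.105).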
